A study of Mus musculus with 7 samples.

How the data were processed

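The 7 samples were from hearts of adult female mice, 3 wild type and 4 double knockout, grouped by the genotype in their labels. The design text names more samples, and those beyond these 7 were not analysed here. Per the labels' protocols, total RNA was extracted with a kit for animal tissue, labelled with Cy3 by the Low Input Quick Amp method with spike-in RNA added, and hybridised to SurePrint G3 mouse arrays of 60-base probes. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, and the values used are its processed signal, a background-corrected intensity on a linear scale, with its flags for spots well above background, saturated or outlying. The other columns used, per the file headers, hold those flags, the probe names, accessions and probe positions, on build mm9. The authors also deposited a table of processed values, used only as an alternative. It holds the same processed signal on a linear scale, rounded and not centred or scaled between arrays, since 99.6% of its cells lay within 0.01 on the log2 scale of the scanner value. Its column medians were 47.7, 45.9 and 50.8 in Wild Type_181, Wild Type_183 and Wild Type_189 and 65.5, 83.3, 80.9 and 61.1 in Mutant_175, Mutant_182, Mutant_187 and Mutant_188.

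Each array held 59305 non-control spots. Between 82 and 146 spots per array were outliers and were left out, and 0 were saturated. The 75th percentile of the processed signal over all non-control spots was 1079, 955 and 1049 in the wild type arrays and 1379, 1666, 1708 and 1245 in the knockout arrays, in the order above. Spots of one probe were averaged, and log2 of the processed signal minus the array's 75th percentile over these probe values was used. Probes well above background on at least 3 arrays were kept, 34481 or 60.9% of all. Each gene was represented by its kept probe with the highest mean over the 7 arrays. Genes were named through the accession of the probe in a table of 49997 genes of assembly GRCm38.p6, used for names only, which matched 32994 probes and gave 1535 of them another name than the file. The file's name was kept otherwise. Scaling each array to its own percentile removes any difference in the total amount of messenger RNA, and measuring relative to 7 spike-in probes was added for that reason. The size of a fold change is uncertain where signals lie near background. A probe not well above background on any array of a group therefore has only a bound. The bound sets the brighter group's mean against the higher of the probe's own signal and the lowest signal well above background on each array. Bounds were taken at the main settings, and fold changes at alternative settings could fall below them. Genes well above background on some arrays of a group keep their fitted fold change.

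Tests used limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9. Each gene was fitted with lmFit and eBayes on all 7 arrays without covariates, with Benjamini-Hochberg adjustment over the 22971 genes and a threshold of 0.05. The 36 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01), adjusted over the lists. A camera test with an estimated correlation and the rotation test fry were alternatives. Replicate numbers are shared by no samples of different groups, so nothing was paired. All arrays lie on 1 slide with 1 scan, so neither was fitted as a batch. Single values per array were compared by exact two-sided permutation over the 35 splits of the arrays, which cannot give a p under 0.029.

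The genes named were Smarca4, Smarca2 and Myc, and the 12 genes with the largest rise and the 12 with the largest fall. These had to be called, with no overlap between groups and well above background on every array of the higher group, and predicted or clone names were left out. From each list up to 3 members with the smallest p were named, or up to 2 where no member was called. Some genes that this rule names are not reported here. Alternatives fixed before the data were examined were quantile normalization, median scaling, a percentile over probes well above background on all arrays, normexp with offset 50 and quantile normalization, the authors' value table, no filter on dim probes, a filter over all arrays, the mean over a gene's probes, a trended robust prior, array weights, and leaving out each array in turn. Spike-in scaling and leaving out Mutant_175 and Mutant_187 together were added after the data were seen.

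The method was tested on simulated data with the spread of these arrays, pooled over both groups, in 10 simulations over 22941 genes. In each, 200 genes were changed and a list of another 40 was shifted by 0.5. Of genes changed by 0.5, 1 and 2 on the log2 scale, 2.24%, 44.9% and 78.9% were called in the right direction, and 3.58% of calls fell on unchanged genes. Camera called the shifted list in 10 of 10 simulations and an unshifted one in 0 of 10. These simulations drew genes independently, and real lists are correlated. They also changed a far smaller share of genes than the 42.1% called in the data. The real spread differed between groups, with a median SD of 0.12 in wild type and 0.26 in knockout. These detection rates therefore do not describe this comparison.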

Results

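Messenger RNA was measured in hearts of adult female mice on 7 one-colour Agilent arrays, 3 from wild type animals and 4 from animals in which Brg1 and Brm were both knocked out. Brg1 (gene Smarca4) and Brm (gene Smarca2) are the alternative ATPase motors of the SWI/SNF chromatin remodelling complexes. Per the design text, Brg1 was deleted in adult cardiomyocytes by tamoxifen, through a Cre recombinase driven by a myosin heavy chain promoter, in animals that already lacked Brm. The labels name cardiomyocytes as the cell type and heart as the source, and they describe a tissue RNA kit without a cell isolation step. Wild type samples are labelled as lacking the transgene and knockout samples as carrying it, and both received tamoxifen. The Brm status of the wild type animals is not given in the sources used here. The wild type samples are titled Wild Type_181, Wild Type_183 and Wild Type_189, and the knockout samples Mutant_175, Mutant_182, Mutant_187 and Mutant_188. Nothing beyond these numbers says that each sample is a separate animal, so the p-values measure the spread between these samples. Each array held 56605 distinct non-control probes, 58.1% to 63.6% of the non-control spots were well above background, and 22971 genes were tested. The small number of arrays limits the precision of every value. Differences are knockout minus wild type on the log2 scale, each array relative to its own 75th percentile, with adjusted p-values from limma.

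Smarca4 was lower in all 4 knockout samples, by a log2 fold change of -1.87 (SE 0.29, adjusted p = 0.0021, n = 3 and 4, limma). Its signal relative to the array's 75th percentile was 34.7, 32.8 and 34.2 in Wild Type_181, Wild Type_183 and Wild Type_189. In Mutant_175, Mutant_182, Mutant_187 and Mutant_188 it was 5.87, 10.26, 14.95 and 8.25. The probe lies on chromosome 9 at 21507751 to 21507810 of mouse build mm9. The other Smarca4 probes, at 21483531 to 21483590 and at 21439194 to 21439253, also fell. The former had a log2 fold change of -1.91, and the latter was not well above background on any knockout array and at least 1.84-fold lower. Smarca2 did not differ, at 0.08 (SE 0.11, adjusted p = 0.59, limma), on a probe at chromosome 19, 26852644 to 26852703. Its other probes, at 26852751 to 26852810 and at 26795294 to 26795353, gave -0.23 and 0.01. Scaled to spike-in RNA, an alternative chosen after the data were seen, Smarca2 was higher in knockout by 0.65 (adjusted p = 0.030, limma). Which exons were removed from either gene is not given in the sources used here, and a gene annotation of build mm9 was not used here. A probe outside the deleted part checks nothing, and whether any probe lies inside it is not known. Neither the remaining Smarca4 signal nor the Smarca2 signal can therefore be read as functional transcript.

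**Figure D1:**
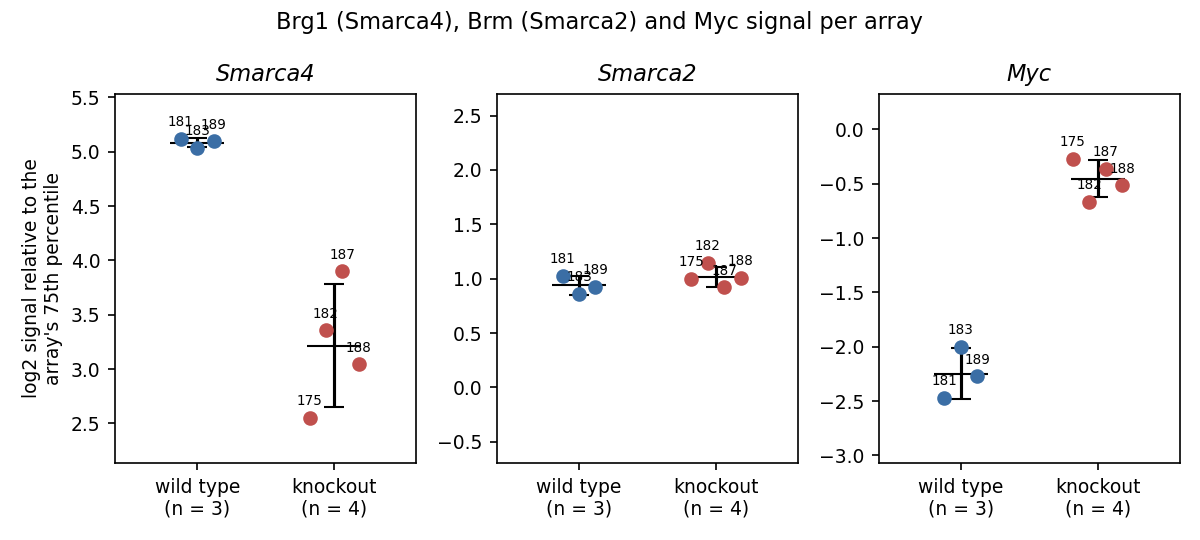
Log2 signal of Smarca4, Smarca2 and Myc relative to each array's 75th percentile (vertical axes, equal spans) in the 3 wild type and 4 knockout arrays (points), with group means and SD (bars). Smarca4 differed by -1.87, Smarca2 by 0.08 and Myc by 1.79; under spike-in scaling Smarca2 differed by 0.65.

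Between wild type and knockout, 3749 genes rose and 5932 fell at an adjusted p under 0.05, and 13290 were not called (limma). A change of at least 2-fold was found for 1945 of the higher and 2295 of the lower genes. The 2 groups of arrays did not overlap in 51.2% of the genes tested, where chance gives 5.7%. The split between higher and lower calls depended on the scaling. Calls were 38.7% higher with the 75th percentile of all probes, 49.5% with the percentile of probes well above background on all arrays, 45.0% after quantile normalization and 83.3% after scaling to spike-in RNA. Spike-in scaling, chosen after the data were seen, added 0.57 to the log2 fold change of the 22941 genes with a value on all arrays (30 genes with a missing value differed by up to 0.1) and moved the median over all genes from -0.12 to 0.44. It called 8516 genes higher and 1705 lower. Of the 9681 calls made before, 5454 were made again in the same direction and the rest were lost. Calls in the opposite direction numbered 0, but a shift this uniform leaves little room for them. Every direction given for a gene or list is therefore relative to the array's 75th percentile. Where a list has 1 pair of counts, the counts over all genes and adjusted over the list alone were equal.

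Among the largest rises were Spp1 (osteopontin, a secreted matrix protein), by 6.57 (SE 0.83, adjusted p = 0.00085, limma), and Lox (lysyl oxidase, which crosslinks collagen and elastin), by 6.06 (SE 0.20, adjusted p = 6.5e-06, limma). Ell3, Nkain2, Mapk8ip2, Mgarp and Rprm also rose, with fitted log2 fold changes of 6.57, 6.39, 6.19, 5.78 and 5.58. In wild type, Spp1, Ell3, Nkain2 and Mgarp were well above background on 1 of 3 arrays and Mapk8ip2 and Rprm on 2 of 3, so these fitted values rest partly on signals near background and give no order of size. The brightest kept probes of another 5 genes were not well above background on any wild type array and have only a lower bound, taken against the lowest signal well above background on each array. These were Frmd3 at least 79.6-fold, Scg2 (secretogranin, a secretory granule protein) at least 34.9-fold, Ereg (epiregulin, a growth factor) at least 22.5-fold, Tmem125 at least 22.4-fold and Ap3b2 at least 17.5-fold higher. These bounds hold at the main settings only. Over the alternatives the lowest log2 fold changes of Scg2, Ereg, Tmem125 and Ap3b2 were 3.47, 2.745, 2.51 and 2.55, below the bounds. The probes of 3 of the genes with the largest rises disagreed in direction or size. Of the 4 Nkain2 probes 3 rose, while the probe that was well above background on all arrays gave -0.42. Under that stricter filter the Frmd3 probe kept gave 0.13 (adjusted p = 0.68, limma) and the Mapk8ip2 probe kept gave 0.94 (called higher).

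The largest falls included Efnb3 (ephrin B3, a membrane ligand), by -6.53 (SE 0.24, adjusted p = 8.6e-06, limma), Ces1d (a carboxylesterase), by -5.73, and Pla2g5 (a secreted phospholipase), by -5.24. Prr33 fell by 6.08, and Eprn, Acsm5, Itgb6 and Tmprss13 had log2 fold changes of -5.81, -5.67, -5.58 and -5.55. In knockout, Prr33 and Eprn were well above background on 3 of 4 arrays, Itgb6 and Tmprss13 on 2 of 4 and Acsm5 on 1 of 4, with the same limit on their fitted values. Gnb3 was at least 53.6-fold, Prss55 at least 41.0-fold, Frmpd3 at least 27.9-fold and Mrgprh at least 13.2-fold lower, each not well above background on any knockout array. Over the alternative settings the smallest falls of these genes were -3.82, -3.74, -3.16 and -2.21 on the log2 scale, smaller than the bounds. Over all genes, 239 called higher were not well above background on any wild type array and 356 called lower on any knockout array. Another probe was called in the opposite direction for 236 called genes.

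Extracellular matrix genes rose together. Of 39 measured, 38 were higher and 0 lower, with a median log2 fold change of 2.68. Postn (periostin) rose by 4.37 (SE 0.25, adjusted p = 3.6e-05, limma) and Eln (elastin) by 3.08, beside Lox above. Fibroblast markers, of which 5 are also in the matrix list, were higher for 12 of 17 and lower for 0, with a median of 1.31 and Mfap5 at 3.07 and Mgp at 1.52. The adjusted p from camera was 3.0e-21 for matrix genes and 5.4e-06 for fibroblast markers, and it was 0.43 for both lists with an estimated correlation. Macrophage and monocyte markers rose, 11 of 20 higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 1.04. Lgals3 rose by 3.12, Mrc1 by 1.41 and Ccr2, the receptor of monocyte chemokines, by 4.25, the last well above background on 1 of 3 wild type arrays. Inflammatory response genes rose, 20 of 32 higher and 1 lower (22 and 1 adjusted over the list alone), with a median of 1.36. The receptor gene Tnfrsf12a rose by 2.66, the chemokine gene Ccl12 by 3.76 and Saa3, an acute phase protein, by 5.47, the last well above background on 1 of 3 wild type arrays. Camera gave adjusted p = 8.9e-06 for macrophage markers and 2.4e-07 for inflammatory genes, and with an estimated correlation adjusted p = 0.55 and 0.46.

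Interferon response genes had 10 of 30 higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.48 and camera adjusted p = 0.0029. With an estimated correlation the adjusted p was 0.66, with spike-in scaling it was 0.081, and the rotation test fry gave 0.17. Mx1 was at least 5.38-fold higher, Ifit2 rose by 1.01 and Gbp6 fell by 1.57. The list's median shift was -0.01 in Mutant_175 and 0.41 to 0.87 in the other knockouts. Lymphocyte markers, 2 of 11 higher and 0 lower (0 and 0 adjusted over the list alone), had a median of 0.73, with Cd3d at 0.87 and Cd3e at 1.11. Their camera adjusted p was 0.021, but 0.59 with an estimated correlation, 0.15 with spike-in scaling and 0.068 without Mutant_187. It was also 0.081 without the filter on dim probes, 0.070 with the mean over a gene's probes and 0.13 by fry. Their median shift was -0.27 in Mutant_175 and 0.72 to 1.32 in the other knockouts. Neutrophil markers, 1 of 10 higher and 2 lower (1 and 1 adjusted over the list alone), gave camera adjusted p = 0.24 and a median of 0.81. Their median shift was 0.94 in Wild Type_181 and -0.38 and -0.29 in the other wild types, and -0.24 in Mutant_175 and 0.73 to 1.67 in the other knockouts. Mmp8 rose by 0.78, Mmp9 fell by 1.65 and Csf3r fell by 0.44, the last at 0.12 with spike-in scaling. Mmp9 was well above background on 3 of 4 knockout arrays. Epicardial and mesothelial markers, 3 of 7 higher and 0 lower (4 and 0 adjusted over the list alone), had a median of 1.81 and camera adjusted p = 0.017. That p was 0.46 with an estimated correlation, 0.12 with spike-in scaling and 0.070 with the filter over all arrays. Their median shift was 4.09 in Mutant_187 and 0.80 to 1.78 in the other knockouts. Krt19 was at least 9.74-fold higher, Krt18 rose by 1.67 and Tbx18 by 0.86.

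Genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, fell nearly as a whole. Of 75 measured, 0 were higher and 72 lower (0 and 74 adjusted over the list alone), with a median of -0.78. Ndufs7, a complex I subunit, fell by 1.22 (SE 0.12, adjusted p = 0.00025, limma), and Cox7a1, a muscle isoform of complex IV, by 1.98. Camera gave adjusted p = 8.1e-14, and 0.57 with an estimated correlation. The fall was smaller after quantile normalization, at a median of -0.43 with 43 lower, and after spike-in scaling, at -0.22 with 8 lower. Fatty acid oxidation genes had 2 of 41 higher and 23 lower (3 and 25 adjusted over the list alone), with a median of -0.88 and camera adjusted p = 0.0024, or 0.77 with an estimated correlation. Acaa2, the last enzyme of the mitochondrial beta-oxidation cycle, fell by 2.63, Ech1 by 1.81 and the nuclear receptor gene Esrra by 0.97. With spike-in scaling the median was -0.32, with 6 higher and 9 lower. The median shift was -0.24 in Mutant_175 and -1.19 to -0.86 in the other knockouts. Genes of mitochondrial fission and fusion had 1 of 21 higher and 10 lower (1 and 12 adjusted over the list alone), with a median of -0.56 and camera adjusted p = 0.0021, or 0.57 with an estimated correlation. Mtfr1 fell by 1.43 and Mtfp1, a fission factor, by 1.75, while Gdap1 was at least 5.86-fold higher. With spike-in scaling this list's median was 0.01. Its median shift was -0.15 in Mutant_175 and -0.63 to -0.54 in the other knockouts.

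Genes of glycolysis moved both ways, 6 of 27 higher and 7 lower. Their median was -0.16, their mean 0.19, and camera (adjusted p = 0.92) pointed up. With spike-in scaling 9 were higher and 4 lower, with a median of 0.41. Slc16a3, a lactate transporter, rose by 4.09 and Eno2, the neuronal enolase, by 4.45, while Pfkfb2, which makes the activator of phosphofructokinase, fell by 2.47. Hypoxia response genes, 5 of 26 higher and 5 lower, gave a median of 0.16 and camera adjusted p = 0.12. That p was 0.035 after quantile normalization, with 7 higher and 1 lower and a median of 0.29, and 0.028 by fry. With spike-in scaling 13 were higher and 0 lower, with a median of 0.73. Besides Lox, Egln3 (a HIF prolyl hydroxylase) rose by 1.46 and Hmox1 (heme oxygenase) by 2.0.

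Potassium channel genes fell, 2 of 25 higher and 20 lower (3 and 20 adjusted over the list alone), with a median of -1.53. Abcc8, the sulfonylurea receptor, fell by 2.37 (SE 0.10, adjusted p = 1.4e-05, limma), Kcnj5, a subunit of the acetylcholine-gated channel, by 1.92 and Kcnq1, of the slow delayed rectifier, by 2.02. Camera gave adjusted p = 7.1e-06, and 0.43 with an estimated correlation, and with spike-in scaling the median was -0.97 with 3 higher and 14 lower. Calcium handling genes had 6 of 34 higher and 16 lower (7 and 18 adjusted over the list alone), a median of -0.47 and camera adjusted p = 0.095. That p was 0.0063 with spike-in scaling, 0.0059 without the filter on dim probes and 0.00066 by fry, each pointing lower. With spike-in scaling the median was 0.10, with 9 higher and 10 lower, so that call is lower only relative to other genes. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 2.19, the calcium channel subunit gene Cacnb2 by 1.89 and the kinase gene Camk2a by 3.50. Conduction and gap junction genes moved both ways, 6 of 37 higher and 13 lower (7 and 14 adjusted over the list alone). Their median was -0.11, their mean -0.21, and camera (adjusted p = 0.92) pointed up. With spike-in scaling 16 were higher and 7 lower, with a median of 0.46. Id2, a transcriptional regulator, rose by 3.59 and Xirp1, of the intercalated disc, by 2.57, while Hcn4, the pacemaker channel, fell by 1.28.

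Sarcomere genes had 6 of 40 higher and 19 lower (7 and 22 adjusted over the list alone), with a median of -0.45 and camera adjusted p = 0.021. That call was lost with an estimated correlation (adjusted p = 0.66), quantile normalization (0.41) and normexp with quantile normalization (0.37). With spike-in scaling the median was 0.11 with 11 higher and 14 lower. Mybpc3, cardiac myosin binding protein C, fell by 2.47 (SE 0.13, adjusted p = 3.0e-05, limma) and Myh7b by 2.36, while Flnc, filamin C, rose by 3.27. A second, much dimmer Myh7b probe, well above background on 1 of 4 knockout arrays, gave -1.26 and was not called. Ventricular cardiomyocyte markers fell, 1 of 19 higher and 15 lower (1 and 16 adjusted over the list alone), with a median of -0.79, and of -0.23 with spike-in scaling. Camera gave adjusted p = 0.0001, and 0.55 with an estimated correlation. Ckm, muscle creatine kinase, fell by 4.34, its mitochondrial counterpart Ckmt2 by 2.26 and Tnni3, cardiac troponin I, by 2.21. Genes of the fetal and stress programme of the heart rose, 13 of 25 higher and 1 lower, with a median of 1.14. Their median shift was 0.54 in Mutant_175 and 1.01 to 2.09 in the other knockouts. Acta2, smooth muscle actin and also in the smooth muscle list, rose by 3.44 (SE 0.14, adjusted p = 1.2e-05, limma), Myl9 by 2.69 and Tgfb2 by 2.08. The member Myh7, chosen after its values were seen, was not called at 0.62, and its other probe fell by 1.99. Camera gave adjusted p = 2.3e-06, and 0.43 with an estimated correlation. The call at the preset correlation held in a planned test without members that are also cell type markers. Atrial markers, 2 of 18 higher and 5 lower, had a median of 0.33 and camera adjusted p = 0.82. Their median shift was -0.56 in Mutant_175, -0.60 in Mutant_188, 0.48 in Mutant_182 and 0.43 in Mutant_187. Nppa, the atrial natriuretic peptide, rose by 0.98, while the channel genes Kcna5 and Kcnj3 fell by 1.6 and 1.53. Skeletal muscle markers had 2 of 10 higher and 5 lower (4 and 5 adjusted over the list alone), a median of -0.31 and camera adjusted p = 0.66, but 0.00067, lower, by fry. Atp2a1 fell by 2.79, and Actn3 was at least 2.20-fold higher.

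**Figure D2:**
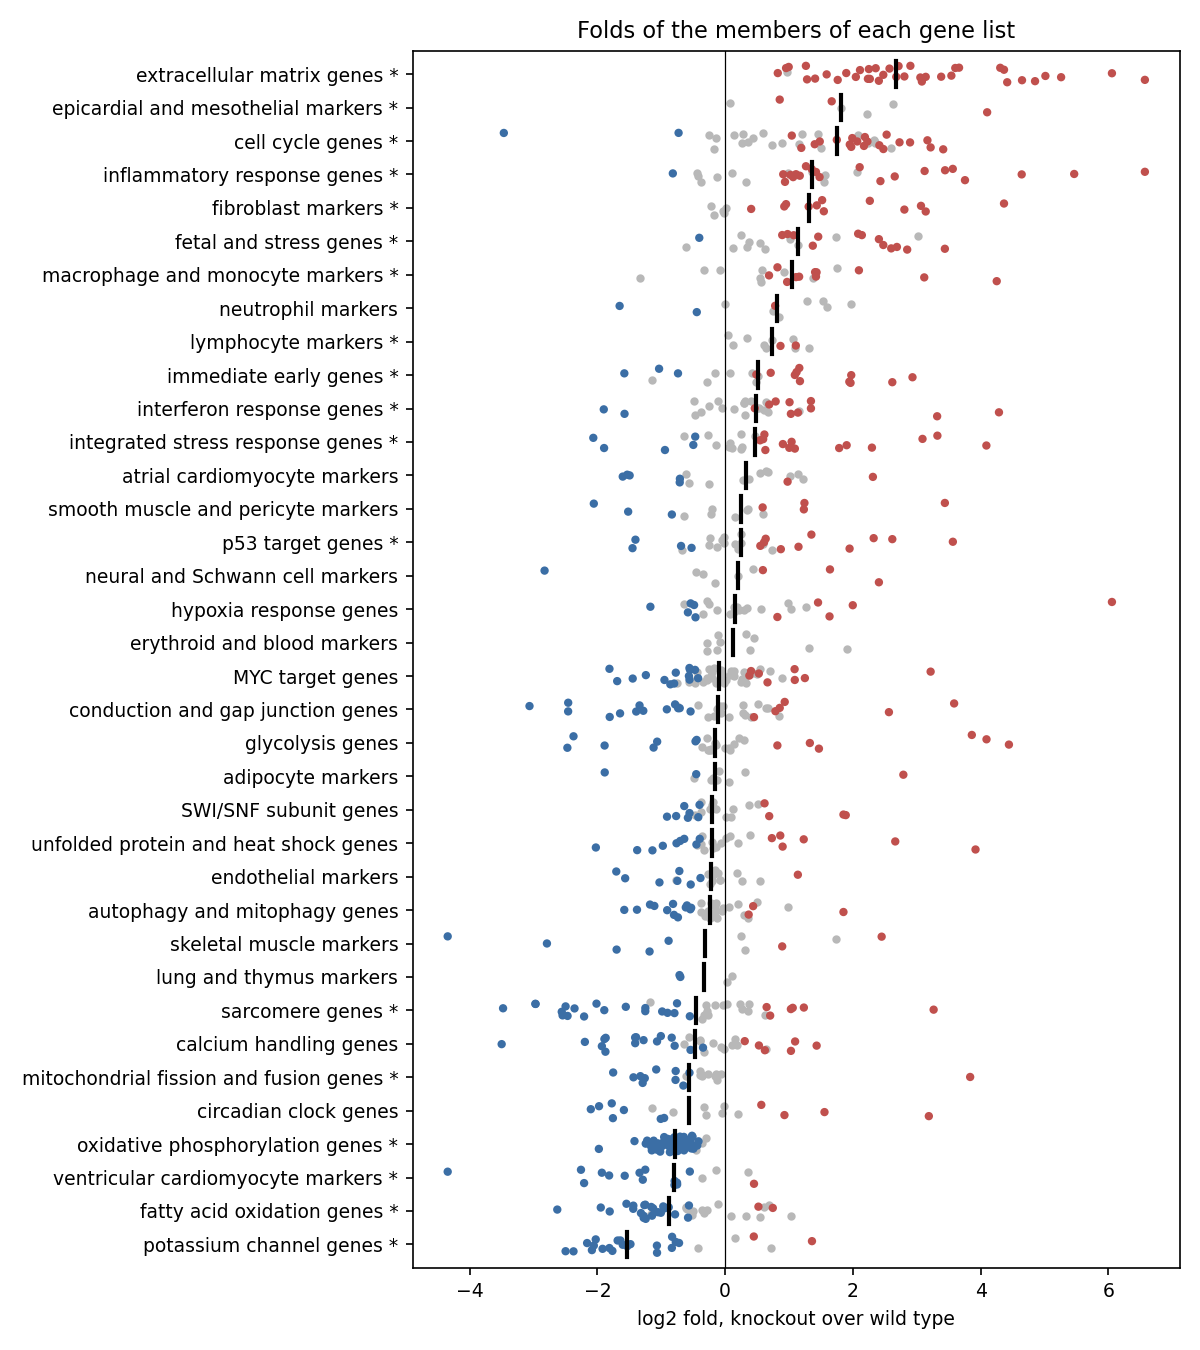
Log2 fold change, knockout minus wild type, of each measured member of the fixed gene lists (horizontal axis; red called higher, blue called lower, grey not called), with each list's median (black bar) and an asterisk where camera with its preset correlation gave an adjusted p under 0.05. Matrix genes have a median of 2.68 and oxidative phosphorylation genes of -0.78; with spike-in scaling these medians were 3.25 and -0.22, and 13 of the 18 negative medians turned positive, among them those of sarcomere, calcium handling, conduction, glycolysis, autophagy, mitochondrial fission and fusion, MYC target and endothelial genes.

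Myc, a proto-oncogene encoding a transcription factor, rose by 1.79 (SE 0.16, adjusted p = 0.00017, limma), with values of -0.66 to -0.27 in knockout against -2.47 to -2.0 in wild type. The probe lies on chromosome 15 at 61821417 to 61821476 of build mm9, and a second one at 61820925 to 61820984 gave 0.96. MYC target genes as a list gave camera adjusted p = 0.88. Of 62 measured, 8 were higher and 14 lower, with a median of -0.09. With spike-in scaling 18 were higher and 4 lower, with a median of 0.48. Hspd1, a mitochondrial chaperonin, fell by 1.45, Sord by 1.69 and Supv3l1 by 0.86. The other SWI/SNF subunit genes had 4 of 24 higher and 7 lower, a median of -0.20 and camera adjusted p = 0.92. With spike-in scaling 8 were higher and 0 lower, with a median of 0.37. Smarcd3, the subunit known as BAF60c, rose by 1.89 (SE 0.10, adjusted p = 3.0e-05, limma) and Brd9 fell by 0.77. Arid1b rose by 0.62 on its brightest probe and gave -0.26 as a mean over its probes.

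Cell cycle genes rose, 20 of 43 higher and 2 lower (21 and 2 adjusted over the list alone), with a median of 1.75, or 1.51 with genes measured in 1 group only at their bound. Cenpa, a centromeric histone, rose by 2.90 (SE 0.34, adjusted p = 0.00058, limma), the checkpoint kinase gene Bub1b by 2.19 and Kif23 by 1.04. Camera gave adjusted p = 9.8e-07, but 0.66 with an estimated correlation, and fry gave 0.096. Mutant_175 stood apart, with a median shift of -0.08 against 1.51 to 2.68 in the other knockouts.

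Integrated stress response genes rose, 14 of 29 higher and 5 lower (14 and 6 adjusted over the list alone), with a median of 0.47 and camera adjusted p = 0.0034, or 0.45 with an estimated correlation. Psat1, of serine synthesis, rose by 4.09 and Nupr1 by 2.30, while Chac1 fell by 2.06. The p53 target genes rose, 10 of 27 higher and 4 lower, with a median of 0.24 and camera adjusted p = 0.020, which was 0.43 with an estimated correlation and 0.055 with spike-in scaling. Cdkn1a, the p21 cell cycle inhibitor, rose by 2.33 on the only 1 of its 3 probes called higher and by 1.09 as a mean over them. Btg2 rose by 2.62 and Phlda3 by 1.95. Immediate early genes rose, 11 of 21 higher and 3 lower, with a median of 0.52 and camera adjusted p = 0.0021, or 0.43 with an estimated correlation. Egr2 rose by 2.94 and Klf6 by 1.16. Genes of the unfolded protein and heat shock response moved both ways, 6 of 27 higher and 9 lower. Their median was -0.21 and their mean 0.02, and camera (adjusted p = 0.92) pointed up. With spike-in scaling 9 were higher and 2 lower, with a median of 0.36. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose signals can be shared, rose by 3.92 and 2.67, while Herpud1 fell by 2.02. Autophagy and mitophagy genes had 3 of 37 higher and 12 lower, a median of -0.23 and camera adjusted p = 0.19. That p was 0.041 without Mutant_175, 0.018 without the filter on dim probes and 0.012 by fry. With spike-in scaling 8 were higher and 4 lower, with a median of 0.335. Gabarapl2 rose by 1.85, while the lysosomal protease gene Ctsd and the mitophagy kinase gene Pink1 fell by 1.38 and 1.58. Circadian clock genes had 4 of 18 higher and 7 lower, a median of -0.57 and camera adjusted p = 0.48. Arntl (Bmal1) rose by 3.19, while Nr1d2 fell by 1.76.

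Camera, at the settings used for all lists, called none of the following lists of other cell types. Endothelial markers had 1 of 20 higher and 7 lower, with a median of -0.22 and camera adjusted p = 0.23, which was 0.041 without the filter on dim probes and 0.0084 by fry. With spike-in scaling the median was 0.35. Aqp1 fell by 1.7, Robo4 by 1.03 and Rgcc by 1.56. Smooth muscle and pericyte markers, 4 of 14 higher and 3 lower, gave a median of 0.25 and camera adjusted p = 0.36, or 0.0027 by fry. Besides Acta2, Cspg4 rose by 1.24, and Abcc9, the sulfonylurea receptor also made by cardiomyocytes, fell by 2.06. Adipocyte markers, 1 of 11 higher and 2 lower, had a median of -0.16, a mean of -0.04 and a camera test (adjusted p = 0.93) that pointed up. Cidea rose by 2.79, Plin4 fell by 1.88, and Lep fell by 0.45 but was at 0.11 with spike-in scaling. Neural and Schwann cell markers, 3 of 9 higher and 1 lower (3 and 2 adjusted over the list alone), had a median of 0.20 and camera adjusted p = 0.54. Uchl1 rose by 2.41, Dbh, of noradrenaline synthesis, fell by 2.83, and Mbp rose by 1.64 on 1 probe with another probe called lower. Erythroid markers had 0 of 10 higher and 0 lower, a median of 0.12 and camera adjusted p = 0.54, with Bpgm at 0.33 and Slc4a1 at 1.32, neither called by limma. With spike-in scaling Bpgm was at 0.89 and called higher (adjusted p = 0.021, limma). The list's median shift was 1.41 in Mutant_175 and -0.99 in Mutant_187. Lung and thymus markers, 0 of 4 higher and 2 lower, had a median of -0.34 (0.23 with spike-in scaling) and camera adjusted p = 0.66, with Cldn18 lower by -0.70 and Scgb1a1 by -0.71, the latter well above background on 2 of 4 knockout arrays.

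**Figure D3:**
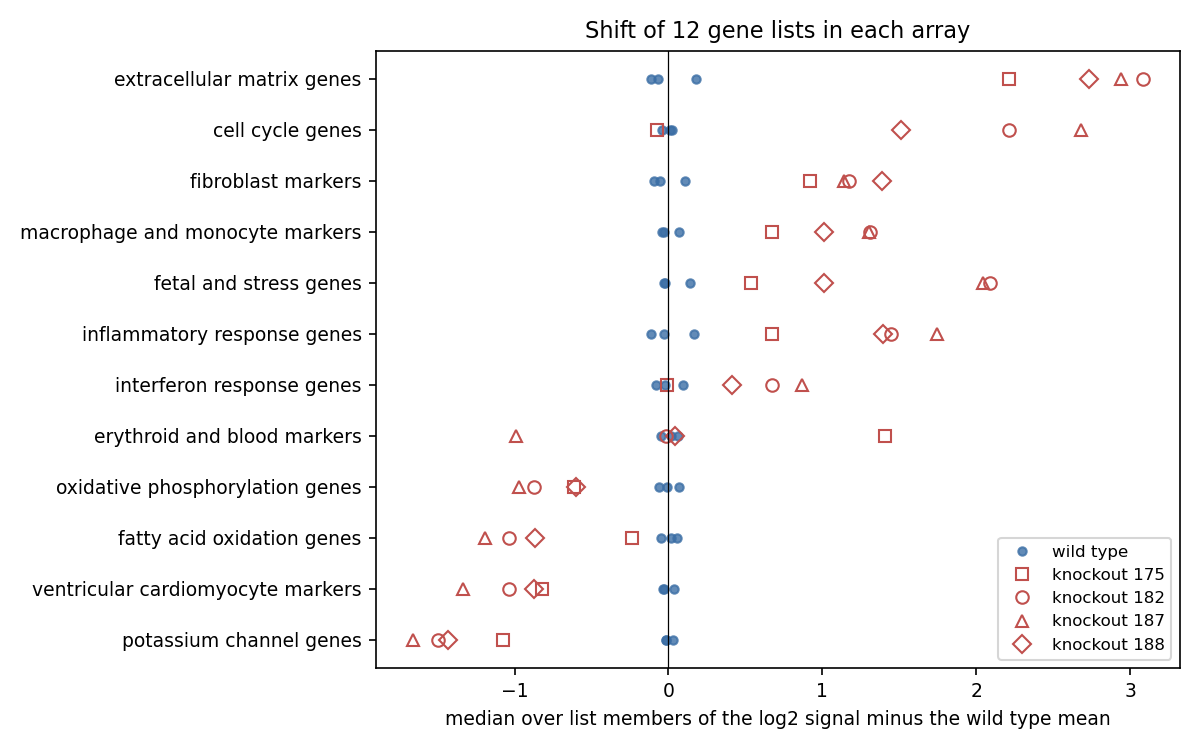
Median log2 shift of 12 gene lists from the wild type mean (horizontal axis) in each of the 7 arrays (points). The lists were chosen for display after their values were seen. Matrix genes lie at 2.21 to 3.09 in the 4 knockouts, cell cycle genes at -0.08 in Mutant_175 and 1.51 to 2.68 in the others; spike-in scaling, not drawn, raises knockout values.

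Some calls of single genes were less firm. With spike-in scaling Supv3l1 (-0.29), Esrra (-0.40), Brd9 (-0.20), Robo4 (-0.46) and Cldn18 (-0.13) were no longer called. As a mean over their probes, Kif23 (1.43), Mbp (0.16), Esrra (-0.50) and Mmp9 (-1.33) were not called either, and Mtfp1 was called at -0.90. Scgb1a1 was at -0.09 and not called after normexp with quantile normalization, a setting that also shrank the folds of genes dim in 1 group, such as Ell3 (3.94). The calls of Cd3d, Cd3e, Csf3r, Krt18, Mmp8, Mmp9 and Scgb1a1 were each lost when any of 2 or more single arrays was left out, with the direction kept. Csf3r gave -0.37 without Wild Type_189, Mmp9 -1.48 without Wild Type_181, Krt18 1.47 without Wild Type_189, Mmp8 0.65 without Wild Type_189 and Cd3d 0.72 without Mutant_182.

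Of the 36 lists, 12 rose and 6 fell by camera with its preset correlation of 0.01. With a correlation estimated from the 7 arrays, 0 lists passed the threshold, and by fry 21 did, which tests each list alone and not against other genes. Knockout arrays varied more between each other than wild type arrays, with a median SD over genes of 0.26 against 0.12. The first principal component, with 69.9% of the variance, separated the groups. The second, with 14.3%, separated Mutant_175 (-74.8) from Mutant_187 (44.8), and without both of these the fit called 4427 genes higher and 6458 lower, an alternative chosen after the data were seen. All wild type arrays lay in 1 row of a single slide and all knockout arrays in the other, so the slide row and the genotype cannot be told apart.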

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

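All explanations weighed here were tested only after the results were seen, except the counts over other splits of the arrays, which were planned.

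The knockout arrays had more labelled messenger RNA signal over the spike-in RNA, which the main comparison of genes did not use and spike-in scaling, added later, did. The 75th percentile of all non-control spots over the spike-ins was -2.99 (SD 0.085, n = 3) on the log2 scale in wild type and -2.46 (SD 0.23, n = 4) in knockout, a difference of 0.537 (exact two-sided permutation p = 0.057, 35 splits). Over averaged probes, as the scaling takes it, the difference was 0.57. Every knockout array lay above every wild type array. No explanation of it was tested.

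In the knockout group, 11 of 168 measures had 1 array far from the other 3, by Dixon's ratio of the gap to the range (above its 95% critical value), where chance gives about 1 in 20, or 8.4. The measures are not independent, as list medians include named genes, so the number given by chance is only a rough guide. The 11 flags are close to it, and any single flag may be chance. Mutant_175 was the array in 6 of the flagged measures, Mutant_187 in 4 and Mutant_188 in 1. Mutant_175 was low in Ell3 (ratio 0.930; log2 -0.63 against 0.98 to 1.10) and in Postn (0.907; 4.87 against 5.65 to 5.73). It was high in Mapk8ip2 (0.916; 1.88 against 0.86 to 0.94), Cd3e (0.846; 2.48 against 1.07 to 1.28) and Bpgm (0.917; 2.19 against 1.32 to 1.39). Its replicate spots varied more than those of the others (0.848), by 3.05% against 1.80% to 1.99%. Mutant_187 was high in Acaa2 (0.975; 6.20 against 5.53 to 5.54) and low in Abcc9 (0.863; 2.13 against 2.63 to 2.71). It was also low in Actn3 (0.882; -4.72 against -4.32 to -4.27) and in the median shift of the circadian clock genes (0.905; -1.23 against -0.45 to -0.36). Mutant_188 was high in the median shift of the adipocyte markers (0.877; 0.73 against -0.51 to -0.36).

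Many genes differed between the groups. Of the 35 splits of the 7 arrays into 3 and 4, only the real one gave as many genes higher (3749, highest other 1419). The same split alone gave as many lower (5932, highest other 1564). A share of 1 in 35 is the smallest these splits can give, so chance is unlikely for these counts but not excluded. Both counts rest on the same split and are not independent. For the number of gene lists called, chance cannot be set aside, since 7 of the 35 splits gave 18 or more, the highest other 22. The row of the slide cannot be told apart from the genotype, because 0 rows held both groups, and neither can the Cre-ERT transgene with tamoxifen, because 0 wild type samples carried it. The loss of Brg1 and Brm, which the design names, stays open beside both.

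Matrix and fibroblast genes rose while cardiomyocyte markers and oxidative phosphorylation genes fell. A lower share of cardiomyocytes would raise markers of every other cell type alike. The fibroblast median exceeded the endothelial one by 1.528 (95% bootstrap interval 0.27 to 2.47, 17 and 20 genes). Only 12 of the 17 fibroblast markers lie outside the matrix list, whose rise is part of the pattern. The interval resamples genes and carries no spread between samples. The bound for this test was first 0.5 and was lowered to 0 after the interval was seen. Under the first bound the test is undecided. It therefore does not decide whether that share is the whole cause. Added fibroblasts with an unchanged profile would raise their other markers as much as the collagens only if those markers were as particular to fibroblasts. Whether they are was not tested. The 12 fibroblast markers outside the matrix list had a median of 0.668 (interval over genes -0.02 to 1.48), below the smallest of 3 collagen folds, 2.27. This does not set added fibroblasts aside, so both explanations stay open. A change within the fibroblasts, or a response of the heart to the knockout, may also account for the pattern and was not tested.

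Oxidative phosphorylation genes fell together, by a list mean of -0.79 relative to the 75th percentile, in all 4 knockouts (exact permutation p = 0.029, the smallest possible). Relative to spike-in RNA the difference was -0.226, with knockout arrays at -0.38 to -0.09 (exact permutation p = 0.114), so how much of the fall comes from the scaling cannot be told. A lower share of cardiomyocytes would lower sarcomere genes as much or more. The sarcomere median stood above that of oxidative phosphorylation genes by 0.330, with a 95% bootstrap interval of -0.42 to 0.57 (40 and 75 genes), which decides nothing. Of the 40 sarcomere genes, 6 were called higher. Ventricular cardiomyocyte markers had a median of -0.79, close to -0.78 for oxidative phosphorylation genes, which does not decide it either. The scaling, a lower share of cardiomyocytes and an effect of the knockout may therefore each contribute.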

How the results depend on the processing

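Spike-in scaling and leaving out Mutant_175 and Mutant_187 together were chosen after the data were seen; the other settings were planned. Slide and scan blocks were not run, as there was 1 of each. No list called with the main settings reversed, and adjusted p-values are given for lists. The cause of a change was not tested unless stated. Spike-in scaling, which adds 0.57 to the log2 fold of genes with a value on all arrays, gave 8516 genes higher and 1705 lower. It gave Smarca2 0.65, Bpgm 0.89 and Myh7 1.18 (each called), and Csf3r 0.12, Lep 0.11 and Gja1 0.39. It turned MYC targets (0.998), conduction (0.7105), SWI/SNF (0.776), unfolded protein (0.998), atrial (0.573) and adipocyte (0.998) lists. Calcium handling was called (0.0063), lower relative to other genes. The calls of p53 target (0.055), interferon (0.081), epicardial (0.124) and lymphocyte (0.148) lists were lost, and 15 lists were called with this scaling. Quantile normalization ended the sarcomere call (0.406) and turned MYC targets (0.967) and SWI/SNF (0.92). Normexp with quantile normalization also ended the sarcomere call (0.366) and turned SWI/SNF (0.957). The percentile over bright probes turned adipocyte (0.972) and the authors' table conduction (0.999). Without the filter, conduction, glycolysis and unfolded protein (each 0.656), atrial (0.873), adipocyte and lung (each 0.739) turned and calcium handling was called (0.0059). A filter over all arrays, which picks another probe, gave Nkain2 -0.42. Lymphocyte markers were not called without the filter (0.081) or with the mean over probes (0.070), nor epicardial markers with the filter over all arrays (0.070). The mean over probes gave Smarca2 -0.046, Arid1b -0.26 and Myh7 -0.69 and turned conduction (0.9985). Array weights turned glycolysis and unfolded protein (each 0.991), and leaving out both knockouts turned them too (0.981 and 0.953).

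With an estimated correlation 0 lists were called: potassium channel 0.431, sarcomere 0.659, fetal 0.431, oxidative phosphorylation 0.569 and fatty acid oxidation 0.766. By fry, calcium handling (0.00066), skeletal muscle (0.00067), smooth muscle (0.0027), endothelial (0.0084), autophagy (0.012) and hypoxia (0.028) lists were also called, cell cycle (0.096), interferon (0.17) and lymphocyte (0.13) lists were not, and conduction (0.484), glycolysis (0.386), atrial (0.216) and adipocyte (0.873) turned. Leaving out 1 array at a time gave 2645 to 4529 genes higher, 4087 to 6775 lower and 17 to 19 lists. Smarca4 ranged from -2.10 to -1.65 and Smarca2 from 0.037 to 0.125. Lists that were not called either way turned at some of these settings, with p of 0.418 to 0.964 for MYC targets, 0.841 to 0.974 for conduction, 0.823 to 0.952 for glycolysis, 0.767 to 0.964 for SWI/SNF and for unfolded protein, 0.102 to 0.936 for erythroid and 0.558 to 0.936 for adipocyte genes. Called lists kept their calls, except lymphocyte markers without Mutant_187 (0.068), and autophagy was called without Mutant_175 (0.041). Dim probes limit the folds of genes measured on few arrays of a group.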

Other observations

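The tests of this part, and its genes other than Arntl and Nr1d2, which the fixed rule named, were chosen after their values were seen. At the cardiac myosin locus on chromosome 14, the long noncoding RNA Mhrt, transcribed antisense to Myh7, fell by 5.15 on the log2 scale (SE 0.31, adjusted p = 4.2e-05, limma), with values of 5.86 to 6.45 in wild type and 0.20 to 1.42 in knockout. Its probe lies at 55593124 to 55593183 of build mm9. The main probe of Myh6, the adult alpha myosin heavy chain, fell by 0.79 and a second one by 3.65. The main probe was not called after quantile normalization (-0.20) or with spike-in scaling (-0.23). For Myh7, the fetal beta isoform, the probes disagreed. The brighter one gave 0.62 (adjusted p = 0.20, limma) and the other, of another transcript, fell by 1.99. The brighter one was called higher without Wild Type_181 (1.07) and with spike-in scaling (1.18). Cenpf fell by 3.46 on its brighter probe (chromosome 1, 191465934 to 191465993). Its other probe (191507765 to 191507824) was not well above background on any wild type array, so it has no exact fold change. That probe was at -6.09 to -5.41 in wild type, -5.39 in Mutant_175 and -2.85 to -2.02 in the other knockouts. The gap junction gene Gja1, connexin 43, gave -0.18 and was not called, and was at 0.39 with spike-in scaling.

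Circadian clock genes moved in opposite directions. Arntl rose by 3.19, Npas2 by 1.56 and Nfil3 by 0.93, while Dbp fell by 1.97, Hlf by 1.77, Nr1d2 by 1.76, Per3 by 1.58 and Tef by 0.95. Nr1d1 at -0.33 and Per1 at -0.29 were not called. These arms peak at opposite times of day, and another hour of collection was put forward as a hypothesis. The median of 5 genes of the Arntl arm minus that of 9 genes of the Dbp and Per arm was higher in knockout by 1.942 (1.13 to 3.21 in the 4 knockouts, exact permutation p = 0.029, the smallest possible). The arms were set beside each other after these genes were seen to move apart, so this value restates the pattern and decides nothing about the hour. The hours of collection are not given in the sources used here, and the hypothesis stays open.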
